A study of Mus musculus with 7 samples.

How the data were processed

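RNA sequencing was performed on total RNA extracted with Trizol from whole mouse spleens, 3 enlarged spleens from mice with the genotype Vav1-iCre;Brca1 F22-24/F22-24 and 4 spleens from wild-type C57BL6 mice, all aged 2 to 3 months. Vav1-iCre expresses the Cre recombinase in blood cells from the stem cell onward, and the Brca1 allele carries recombination sites around exons 22 to 24. The labels name each library as a separate spleen and say no more about how the animals were matched, so p-values measure the spread between these spleens. Only the mutant group is described as carrying the recombinase and the altered Brca1 allele and as having enlarged spleens. Effects of these 3 cannot be told apart in a comparison of mutant with wild type. Nor can any other difference that goes with the group, such as strain background, which is named above for wild type only.

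Per the submitters' processing notes, bcl2fastq 2.17.1.14, TopHat2 2.0.12, featureCounts from Subread 1.4.6 and edgeR were used with the mouse build mm10. The order and settings of these tools, and whether counting used strand, are not given in the sources used here. The authors deposited raw counts per gene, with gene symbols and coordinates, and a table of CPM for the same 24062 genes. In that deposited CPM table each library's values were the raw counts multiplied by 1 constant, with a largest relative deviation of 5.1e-15. Those constants matched effective library sizes from TMM scaling over all genes with a count, to within 2.22e-16, and the columns sum to 849108 to 1164022. The 4455 genes with 0 counts in every library were the ones without a deposited CPM value. No column of per-sample values was left unused.

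Total counts per library ranged from 26889712 to 63612532. A count of 0 allows up to 3 counts, which corresponds to 0.0279 CPM over the mutant group and 0.017 CPM over the wild-type group. Such floors, and the 95% exact binomial intervals given for ratios of few counts, cover counting error only, because reads without molecular identifiers are not independent molecules. Among genes with at least 10 counts in total, 105 genes fell into 47 sets with identical counts in all libraries, such as Hba-a1 with Hba-a2 and Ccl21a with Gm1987. Counts of such copies, and of genes whose spans overlap, are uncertain because reads can be shared between them.

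The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the raw counts, with TMM factors, filterByExpr and group as the only term, over all 7 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and those changed at least 2-fold were counted apart. Log2 fold changes are mutant minus wild type, and the standard error (SE) is the log2 fold change divided by the square root of the F statistic. CPM values in the text use these TMM factors and are means ± SD with n = 3 mutant and n = 4 wild-type libraries. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the 24 lists with at least 3 tested members. The 25 lists were fixed before the data were examined, as were the groups, the tests and most alternatives. The lists cover the cell types a spleen can hold, tissues that could be carried over (pancreas, fat, liver, muscle), sex-linked genes, and pathways of cell division, homologous recombination, p53, interferon and inflammation. Each list is described by the median log2 fold change of its tested members.

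Named genes followed a fixed rule. They were Brca1 and Vav1, the 10 genes with the largest increase and the 10 with the largest decrease among called genes with a mean of at least 5 CPM and no overlap between the groups, without clone names or antigen receptor segments, and up to 3 members of each list with the smallest p. That gave 91 genes. Other genes named in the text were chosen after their values were seen, as list members that went against their list or as examples.

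On simulated counts for the mutant against wild-type comparison, with 200 of 15188 genes changed and 14882 tested, the test called 6.19% of genes changed 2-fold and 65.7% of genes changed 4-fold. Of its calls, 4.05% were unchanged genes and 0 had the wrong direction. In the data 57.4% of genes were called, far more than were changed in the simulation. The adjusted threshold is stricter when few genes change, so the simulated shares do not give the share of changes missed here. Alternatives covered size factors of the RLE kind, library size alone, removal of globin genes, other filters, DESeq2 1.42.0, edgeR's exact test, limma-voom with and without sample weights, a robust prior, limma on log2 of the deposited CPM plus 1 or plus 0.1, the replicate number as a block, an adjusted p under 0.01, and each library left out in turn. For lists they also covered camera with an estimated correlation, camera with ranks and fry. Where camera compares a list with the other genes, fry asks whether the list changes at all, so its p answers another question. A further 4 alternatives were chosen after seeing the data: wild-type 1 and 2 left out, mutant 1 and wild-type 3 left out, the erythroid list mean as a covariate, and 1 gene kept of each identical set.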

Results

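Transcripts of whole spleens were counted in 3 enlarged spleens from mice carrying a blood-specific deletion of Brca1 exons 22 to 24 and in 4 wild-type spleens. Brca1 encodes a repair protein needed for homologous recombination. The series asks how different Brca1 mutations affect blood stem cells, and the comparison available here is mutant against wild-type spleen. The mutant libraries held 51680976, 30660980 and 35670644 counts, and the wild-type libraries 26889712, 27852545, 41263918 and 63612532. No pair of libraries agreed within sampling noise.

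The targeted gene comes first as a check of the labels. Brca1 (chromosome 11, 101488764 to 101551955, minus strand, mm10) stood at 52.5 ± 13.3 CPM in the mutant and 38.7 ± 26.4 CPM in wild type (n = 3 and 4), a log2 fold change of 0.44 (SE 0.51, adjusted p = 0.49, edgeR). Counts summed over the gene cannot show the loss of exons 22 to 24, so this level neither supports nor contradicts the genotype labels. Per library, Brca1 stood at 67.5, 47.1 and 42.7 CPM in the mutant and at 46.2, 72.8, 15.7 and 20.2 CPM in wild type. Without wild-type 1 and 2, left out after seeing the data, its log2 fold change was 1.55 (adjusted p = 0.0129, against a range of 0.0129 to 0.938 over its alternatives), and leaving out 1 library gave 0.17 (without wild-type 3) to 0.94 (without wild-type 2). Vav1, whose regulatory sequence drives the recombinase, had a log2 fold change of -0.26 (SE 0.18, adjusted p = 0.24, edgeR). Scaled by library size alone, Vav1 passed the threshold at -0.52 (adjusted p = 0.0482, range 0.0482 to 0.866 over its alternatives), and leaving out 1 library gave -0.37 to -0.03 (without mutant 1).

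By list medians, genes of immature T cells, cell division and homologous recombination stood higher in the mutant spleens, and genes of B, NK, dendritic, monocyte and stromal cells stood lower. These lists were called by camera with a preset correlation and none with an estimated correlation (adjusted p = 0.553 for each). Of 15188 genes tested, 4334 rose and 4390 fell in the mutant, 57.4% in all, by edgeR's quasi-likelihood test at an adjusted p under 0.05. At least 2-fold changes were found for 2607 genes that rose and 3509 that fell. The groups did not overlap for 9373 genes (61.7%), where chance gives 5.71%. Genes that rose made up 49.7% of calls with TMM and 38.1% with library size alone, a scaling that placed the median gene at -0.26 instead of -0.02 on the log2 scale.

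The first principal component held 75.7% of the variance in log2 CPM and separated the genotypes. Correlations of log2 CPM across genes, which are not independent replicates, were 0.957 to 0.989 between wild-type libraries, 0.934 to 0.959 between mutant libraries and 0.795 to 0.884 between the groups. The median SD of log2 CPM was 0.395 in the mutant and 0.204 in wild type.

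**Figure D1:**
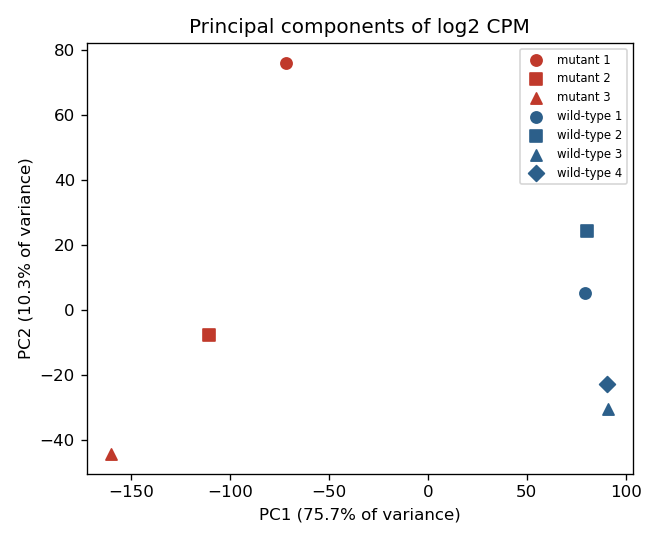
Principal components of log2 CPM, PC1 (75.7% of variance) on the x axis and PC2 (10.3%) on the y axis, with 1 point per library, red for mutant and blue for wild type. The 3 mutant libraries lie at PC1 of -71.7 or below and the 4 wild-type libraries at 79.7 or above.

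Immature T cell genes had the highest list median over all libraries. The early B cell list was next at 3.30, and stood above it without wild-type 4 (3.51 against 3.43). Of 14 immature T cell members, 12 rose and 1 fell, the same numbers when adjusted over the list alone (limma-voom called 10 and 1), with a median log2 fold change of 3.49 (camera adjusted p = 1.01e-04, but adjusted p = 0.553 with an estimated correlation). Rag1, which cuts antigen receptor genes for rearrangement, went from 1.24 ± 0.128 CPM to 467 ± 241 CPM (log2 fold change 8.55, SE 0.49, adjusted p = 1.45e-04, edgeR). Arpp21, a gene of developing thymocytes, rose by 8.10 (SE 0.44) and Themis, needed for thymocyte selection, by 2.44 (SE 0.16) on the log2 scale. Notch1, the receptor that commits progenitors to the T lineage, stood at 520, 1304 and 933 CPM in the mutants and at 78.1 to 91.9 CPM in wild type. The member that fell was Cd1d1, which presents lipids to NKT cells (-1.75, SE 0.18). Hes1, a Notch target, did not pass (0.74, SE 0.34, adjusted p = 0.0988, edgeR).

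In the general T cell list 19 of 28 members rose and 3 fell, or 20 and 4 adjusted over the list alone, with a median of 1.72 (camera adjusted p = 2.01e-04, but adjusted p = 0.553 with an estimated correlation). Tcf7, a transcription factor of early T cells, rose from 204 ± 26.3 CPM to 2171 ± 716 CPM (3.41, SE 0.26), and Gata3, a T lineage factor, rose by 3.09 (SE 0.26). Cd3e, Cd8a and Lck rose by 1.73, 1.59 and 2.21. The members that fell were Foxp3 (-6.04, SE 0.47), the factor of regulatory T cells, Ccr7 (-3.46, SE 0.50), which guides mature naive T cells, and Icos (-1.43, SE 0.34), a costimulatory receptor of activated T cells. Several predicted genes overlap the Foxp3 span in the deposited coordinates, so its level is uncertain. Cd4 stood at -0.70 (SE 0.26, adjusted p = 0.0506, edgeR).

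The early B cell list went both ways. Of 7 tested members, 4 rose (Rag1, Rag2, Dntt and Sox4) and 2 fell, with the same numbers adjusted over the list alone, and the list was not called (median 3.30, camera adjusted p = 0.189). Its median was 1.89, 1.48 and 1.75 without mutant 1, 2 and 3, and 0.083 without a filter on low counts, and fry called it (adjusted p = 0.00411, range 0.00411 to 0.553 over its alternatives). Rag1, Rag2 and Dntt also belong to the immature T cell list. Vpreb3, a chaperone of the B cell receptor precursor, fell by 6.44 (SE 0.43) on the log2 scale.

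Mature B cell genes fell across the whole list. All 23 tested members fell, the same number adjusted over the list alone, with a median of -5.19 (camera adjusted p = 2.12e-08, but adjusted p = 0.553 with an estimated correlation). Cd79b, a signalling chain of the B cell receptor, went from 575 ± 78.0 CPM to 21.3 ± 12.6 CPM (-4.75, SE 0.43). Spib, a B cell transcription factor, fell by 5.19 (SE 0.32), and Tnfrsf13c, the receptor for the survival factor BAFF, fell by 3.79 (SE 0.26). Of 11 plasma cell genes, 7 fell, among them Xbp1 (-0.94, SE 0.18) and Prdm1 (-2.53, SE 0.53), and Sdc1 rose (2.79, SE 0.26), with the same numbers adjusted over the list alone. That list was not called (median -1.60, camera adjusted p = 0.116), but it passed without mutant 3 (-2.14, camera adjusted p = 0.0362, range 0.0187 to 0.553 over its alternatives).

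NK and cytotoxic genes had a median of -4.91, with 15 of 18 members lower and 1 higher, or 16 and 1 adjusted over the list alone (camera adjusted p = 6.74e-06, but adjusted p = 0.553 with an estimated correlation). Klre1 (-7.36, SE 0.45) and Klrg1 (-6.06, SE 0.40), receptors of NK cells, fell, while Gzma, a granule protease, rose from 55.1 ± 4.92 CPM to 373 ± 141 CPM (2.76, SE 0.25). Ly49 receptor genes of NK cells were among the 10 largest decreases. Klra18 and Klra4 had 0 counts in all mutant libraries and 11.5 ± 2.13 and 9.69 ± 1.42 CPM in wild type, which makes them at least 412-fold and 347-fold lower against a floor of 3 counts over the mutant group. Klra7 had 1 mutant count and a pooled ratio of 1110 (95% interval 198 to 43700), and Klra23 and Klra13-ps, with 5 mutant counts each, had ratios of 347 (149 to 1070) and 339 (145 to 1040). These Klra genes overlap other Klra spans and may share reads, so their separate values are uncertain.

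Dendritic cell genes had a median of -4.28, with 13 of 16 members lower and 1 higher, or 14 and 1 adjusted over the list alone (camera adjusted p = 3.57e-05, but adjusted p = 0.553 with an estimated correlation). Flt3, the growth factor receptor of dendritic cells and progenitors, fell by 5.29 (SE 0.64), and Siglech (-6.36, SE 0.54) and Cd209a (-7.36, SE 0.75) fell too. The member that passed higher was Ccr9 (2.22, SE 0.78), a chemokine receptor also held by the immature T cell list. Ccr9 stood at 195, 8.64 and 121 CPM in the mutants and at 23.3 ± 3.68 CPM in wild type, with mutant 2 below each wild-type library, and limma-voom called 0 dendritic members higher. Monocyte and macrophage genes had a median of -2.21, with 16 of 19 lower, also when adjusted over the list alone (camera adjusted p = 7.43e-05, but adjusted p = 0.553 with an estimated correlation). Cx3cr1, a monocyte chemokine receptor, stood at 30.3 ± 3.18 CPM in wild type and at 1.57, 1.20 and 0.716 CPM in the mutants (-4.69, SE 0.31), Itgam fell by 2.54 and Lyz2, the macrophage lysozyme, by 2.87.

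Red pulp macrophage genes had a median of -1.49, with 6 of 17 lower on either adjustment, including adjusted over the list alone (camera adjusted p = 0.00222, but adjusted p = 0.584 with an estimated correlation). Marco, a scavenger receptor of splenic macrophages, fell by 2.80 (SE 0.41), Timd4 by 3.58 (SE 0.51) and Siglec1 by 4.18 (SE 0.85). Marco and Siglec1 also mark macrophages of the marginal zone. Cd163, a scavenger receptor of red pulp macrophages, also fell (-3.25, SE 0.78), while Spic (-0.78, SE 0.61), Vcam1 (-1.03, SE 0.53), Hmox1 (-0.82, SE 0.46), Slc40a1 (-1.19, SE 0.61) and Treml4 (-1.51, SE 0.81) did not pass in edgeR. DESeq2 called 10 members lower, limma-voom 12 and edgeR's exact test 10. For neutrophil genes 7 of 24 fell, or 6 adjusted over the list alone, with a median of -1.54 (camera adjusted p = 0.00742, but adjusted p = 0.655 with an estimated correlation). Of all 15188 genes tested 4390 fell, so the neutrophil count is near the share over all genes and the red pulp count little above it. Mmp9, Cxcr2 and Csf3r fell by 2.92, 2.48 and 3.13. Relative to the wild-type mean, the neutrophil list median was -0.90, -0.75 and -5.51 in the 3 mutant libraries. Without mutant 3 the neutrophil and red pulp medians were -0.97 and -0.96.

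Megakaryocyte and platelet genes had a median of -2.05, with 15 of 20 lower and 1 higher, or 16 and 1 adjusted over the list alone (camera adjusted p = 0.00222, but adjusted p = 0.577 with an estimated correlation). Nrgn, Slc35d3 and Thbs1 fell by 2.97, 2.34 and 1.67, and P2rx1, an ATP-gated channel, passed at 1.84 (SE 0.56). P2rx1 stood at 7.59, 36.7 and 61.6 CPM in the mutants and at 9.83 ± 0.665 CPM in wild type, with mutant 1 below each wild-type library, and limma-voom called 0 members of the list higher. For mast cell, basophil and eosinophil genes 8 of 14 fell, also adjusted over the list alone, with a median of -2.82 (camera adjusted p = 0.00375, but adjusted p = 0.553 with an estimated correlation). Epx and Prg2, eosinophil granule proteins, fell by 5.57 (SE 0.94) and 4.92 (SE 0.86), and Il5ra, the receptor for their growth factor, fell by 3.13.

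Stem and progenitor genes had a median of -1.64, with 16 of 22 lower and 2 higher, the same adjusted over the list alone (camera adjusted p = 0.00186, but adjusted p = 0.553 with an estimated correlation). Hlf, a transcription factor of stem cells, went from 5.92 ± 0.529 CPM to 0.231 ± 0.146 CPM (-4.60, SE 0.45), and Ly6a, the Sca-1 antigen, fell by 3.20 (SE 0.54). The members that rose were Myb (2.72, SE 0.32), a factor of progenitors and thymocytes, and Cdk6 (1.79, SE 0.45), a cell cycle kinase. Stroma and endothelium genes had a median of -1.06, with 12 of 20 lower and 1 higher, Pdgfrb (1.57, SE 0.33), the same adjusted over the list alone (camera adjusted p = 0.00267, but adjusted p = 0.553 with an estimated correlation). The chemokines that organise lymphoid zones, Cxcl13, Ccl19 and Ccl21a, fell by 4.10 (SE 0.33), 3.85 (SE 0.46) and 4.11 (SE 0.30), and Ccl21a had counts identical to Gm1987.

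Genes of S, G2 and M phase rose, 25 of 33 members with 0 lower, or 27 adjusted over the list alone, at a median of 1.86 (camera adjusted p = 1.67e-07, but adjusted p = 0.553 with an estimated correlation). Mcm3 and Mcm6, parts of the replicative helicase, rose by 1.97 (SE 0.28) and 1.98 (SE 0.31), and Bub1b, a spindle checkpoint kinase, rose by 2.34 (SE 0.34). Mki67, the common marker of dividing cells, did not pass (1.04, SE 0.68, adjusted p = 0.219, edgeR). Relative to the wild-type mean the list median was 2.00, 2.18 and 2.01 in the mutants and 0.49, 1.03, -0.96 and -0.56 in wild-type 1 to 4, and the erythroid list median was also above that mean in wild-type 1 (1.01) and wild-type 2 (1.98).

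Genes of homologous recombination and the Fanconi pathway rose in 26 of 31 members with 0 lower, or 27 adjusted over the list alone, at a median of 1.21 (camera adjusted p = 3.57e-07, but adjusted p = 0.553 with an estimated correlation). The list median relative to the wild-type mean was 1.12 to 1.24 in the mutants and 0.12, 0.26, -0.25 and -0.11 in wild-type 1 to 4, and in wild type it had the same signs as that of the S, G2 and M phase list. Exo1, an exonuclease that resects DNA ends, went from 9.97 ± 3.77 CPM to 59.6 ± 11.8 CPM (2.58, SE 0.33). Nbn and Mre11a, partners in the complex that senses DNA breaks, rose by 1.12 (SE 0.13) and 1.04 (SE 0.14). Brca2, a partner of Brca1 in repair, did not pass (1.21, SE 0.46, adjusted p = 0.0544, edgeR). Among 26 p53 target genes 10 rose and 3 fell, or 9 and 3 adjusted over the list alone, and the list was not called (median 0.46, camera adjusted p = 0.0979), but it passed without mutant 3 (0.77, camera adjusted p = 0.00323, range 0.00323 to 0.655 over its alternatives). Aen, Ei24 and Zmat3 rose by 1.47 (SE 0.12), 1.03 (SE 0.11) and 1.67 (SE 0.20). Cdkn1a, the cell cycle inhibitor induced by p53, stood at 265, 96.3 and 30.5 CPM in the mutants and 7.79 to 9.60 CPM in wild type.

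Interferon response genes had a median of -2.24, with 15 of 24 lower, also adjusted over the list alone (camera adjusted p = 2.06e-05, but adjusted p = 0.553 with an estimated correlation). Stat2, a transcription factor of interferon signalling, fell by 1.86 (SE 0.13), and Ddx58, a sensor of viral RNA, by 2.39 (SE 0.20). Relative to the wild-type mean the interferon list median was -1.39, -2.53 and -4.51 in mutants 1 to 3, beside -1.30, -2.43 and -3.97 for monocyte and macrophage genes and -3.35, -4.27 and -6.61 for dendritic cell genes. For inflammatory cytokine genes 9 of 14 fell on either adjustment, including adjusted over the list alone, with a median of -1.29 (camera adjusted p = 0.0157, but adjusted p = 0.553 with an estimated correlation). Nlrp3, an inflammasome sensor, and Il12b, a cytokine of dendritic cells, fell by 3.56 and 4.04. Immediate early and heat shock genes were not called as a list (median -0.85, camera adjusted p = 0.116), with 7 of 18 lower and 1 higher, or 3 and 0 adjusted over the list alone. Without mutant 1 that list was called (-1.36, camera adjusted p = 0.0238, range 0.0238 to 0.655 over its alternatives). Egr2, Fosb and Zfp36 fell by 2.43, 2.08 and 1.91.

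**Figure D2:**
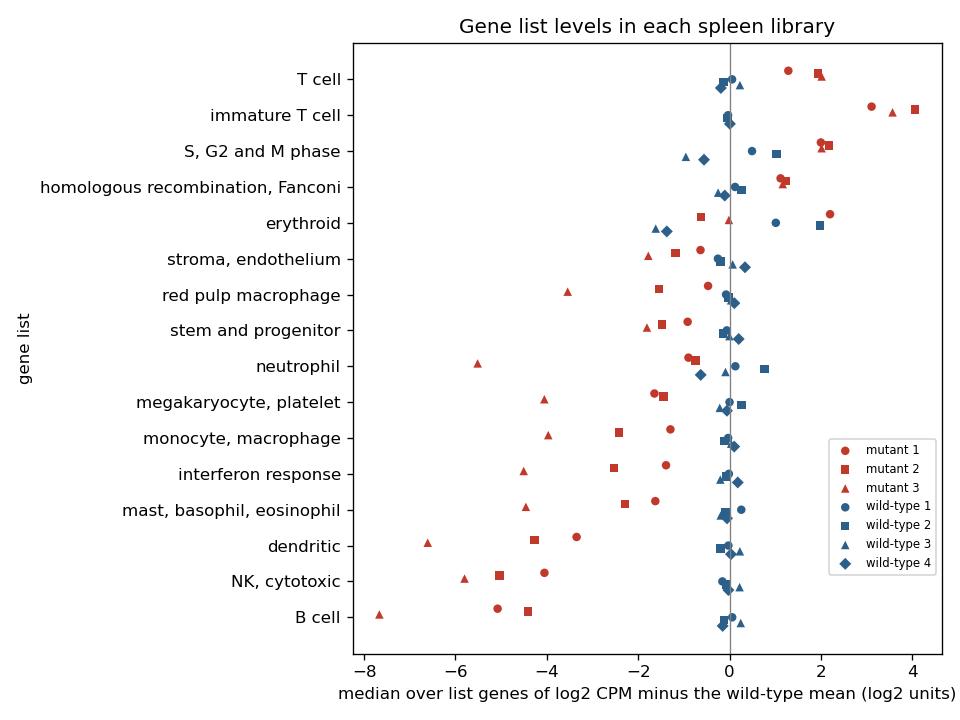
Median over each list's genes of log2 CPM minus the wild-type mean (x axis, log2 units) for 16 gene lists (y axis), with 1 point per library, red for mutant and blue for wild type. The B cell list lies at -5.08, -4.41 and -7.67 in the mutants, and the immature T cell list at 3.11, 4.06 and 3.57.

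Erythroid genes differed between spleens of the same genotype more than between the groups. Of 30 members, 0 passed in edgeR, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom (median 0.14, camera adjusted p = 0.32). Tfrc, the transferrin receptor, had a log2 fold change of 1.35 (SE 0.71, adjusted p = 0.14, edgeR), Car1 of 1.48 (SE 0.89) and Bpgm of -0.99 (SE 0.87). The list median relative to the wild-type mean was 2.20, -0.62 and -0.015 in the mutants and 1.01, 1.98, -1.62 and -1.37 in wild-type 1 to 4. Of 9 heme synthesis genes 0 passed in edgeR, 0 had an unadjusted p under 0.05, and 0 were called by DESeq2 or limma-voom (median 0.34, camera adjusted p = 0.543). Cpox, Alad and Alas1 stood at 1.24, 0.73 and -0.18. Without wild-type 2 Tfrc passed at 2.04 (adjusted p = 0.0359, edgeR, range 0.00143 to 0.551 over its alternatives) and the erythroid list was called higher (median 1.11, camera adjusted p = 0.0262, range 7.55e-05 to 0.873 over its alternatives). Without both wild-type 1 and 2 the erythroid list median was 2.47 and the heme list was also called (2.12, camera adjusted p = 0.0272, range 0.0272 to 0.984 over its alternatives). Alad then passed at 2.33 (adjusted p = 0.00667, edgeR, range 0.00667 to 0.815). With the erythroid list mean as a covariate, Tfrc, Bpgm, Cpox and Alad passed at 1.26, -1.07, 0.80 and 0.84, and Alas1 passed with library size alone (-0.43, adjusted p = 0.0491, range 0.0491 to 0.901). Tfrc and Bpgm are members of the erythroid list, so each was adjusted for a mean that contains it. Leaving out 1 library gave 0.053 (without mutant 1) to 1.93 (without wild-type 2) for Cpox and -0.46 to 1.24 for the heme list, at the same libraries. It gave 0.017 (without mutant 1) to 1.96 (without mutant 2) for Car1 and -1.81 (without mutant 1) to -0.014 (without wild-type 2) for Bpgm.

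The 10 largest increases named by the rule were Vgll1, Necab1, Fam183b, Fbp1, Bex1, Vrtn, Oprk1, Gfra1, Rag1 and Arpp21. Gfra1, a receptor for glial cell line-derived factor, went from 0.582 ± 0.197 CPM to 221 ± 120 CPM (8.56, SE 0.58, adjusted p = 1.45e-04, edgeR). Most of the others varied widely between mutants. Necab1, a calcium-binding protein, stood at 7.88, 53.4 and 298 CPM and Fbp1, an enzyme of gluconeogenesis, at 0.577, 20.5 and 92.3 CPM. Vgll1 and Fam183b had 3 wild-type counts each, with pooled ratios of 1850 (95% interval 631 to 8950) and 641 (219 to 3110). Bex1, Vrtn and Oprk1, with 4, 4 and 5 wild-type counts, had pooled ratios of 520 (203 to 1910), 498 (194 to 1830) and 401 (171 to 1240). Fbp1 lost its call with limma-voom (adjusted p = 0.0527, range 1.5e-10 to 0.0527 over its alternatives).

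Pancreatic enzyme transcripts were high in wild-type 2. The pancreas list held 2.04% of all counts there, 0.0731% in wild-type 1 and at most 0.006% in the other libraries. Of 12 tested members 11 fell, also adjusted over the list alone, and the list was not called (median -11.19, camera adjusted p = 0.105), though its median was -6.49 without wild-type 2 and it passed without wild-type 4 (camera adjusted p = 0.0198, range 0.00471 to 0.7 over its alternatives). limma-voom called 0 members with 0 at an unadjusted p under 0.05, edgeR's exact test called 12, and DESeq2 gave them no p. Cel, Prss2 and Rnase1, with Gp2 and Klk1 from the same rule, were among the 10 largest decreases. Cel, a pancreatic lipase, stood at 1516 CPM in wild-type 2, 36.2 in wild-type 1, 0.642 in wild-type 3 and 0.172 in wild-type 4, against 0.121 ± 0.0218 CPM in the mutant (-11.61, SE 3.76, adjusted p = 0.0302, edgeR). Prss2 (-11.34, SE 3.62), Rnase1 (-10.91, SE 3.66) and Gp2 (-10.52, SE 2.95) had the same shape, as did Ctrb1 (-11.21) and Cela2a (-11.50). Each of these 6 genes lost its call when any 1 mutant library was left out, with adjusted p between 0.0541 and 0.101. Leaving out 1 library brought the log2 fold changes of Gp2, Ctrb1 and Cela2a as near to zero as -6.44, -7.091 and -6.885. Klk1, a kallikrein, stood at 146 CPM in wild-type 2 and 3.87 to 8.41 CPM in the other wild-type libraries (-8.93, SE 2.08). It lost its call in limma-voom with sample weights (adjusted p = 0.166).

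Of 10 fat, liver and muscle genes 1 rose (Apoa2, 2.22, SE 0.32) and 1 fell (Tnnt3, -2.34, SE 0.32), the same adjusted over the list alone, and the list was not called (median -1.48, camera adjusted p = 0.615). Plin1 stood at -2.10 (SE 1.47, adjusted p = 0.253, edgeR), at -7.95 without mutant 1 and at -0.77 without wild-type 4, where it reached 2.10 CPM. Of the sex-linked list only Xist was tested. Xist, transcribed from the inactive X chromosome, stood at 1.59 CPM in mutant 1 and 3.39 CPM in wild-type 3 and at 1668 to 2196 CPM in the other 5 libraries (log2 fold change -0.13, SE 1.87, adjusted p = 0.96, edgeR). The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty had 1443 to 6503 counts in mutant 1 and wild-type 3 and at most 10 in the other libraries, so each group holds 1 library with Y-linked transcripts. The labels give no sex, and sex was not a term in the model.

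In all, 16 of 24 lists were called with the preset correlation, 4 higher and 12 lower. With an estimated correlation 0 were called and 0 had an unadjusted p under 0.05, while fry called 17 and camera with ranks 16. For each called list that estimated-correlation p was the highest over its alternatives, and the lowest ran from 1.94e-18 for S, G2 and M phase genes to 0.00631 for inflammatory cytokines. Other splits of the 7 libraries into 3 and 4 gave up to 22 called lists, whereas the highest other split gave 0 called genes. These splits mix the genotypes and so carry part of their difference. The number of list calls therefore cannot decide whether the list calls follow the genotypes.

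**Figure D3:**
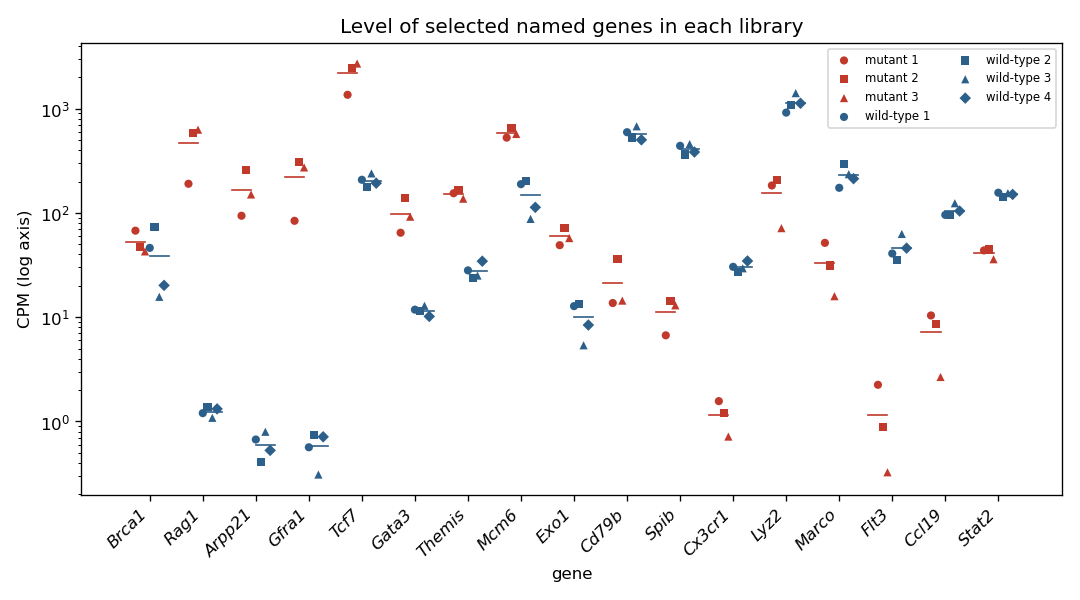
CPM (y axis, log scale) of 17 named genes (x axis) in each library, red for mutant and blue for wild type, with horizontal lines at the group means. Rag1 lies at 190 to 628 CPM in the mutants and at 1.08 to 1.37 CPM in wild type, and Brca1 overlaps between the groups.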

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

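The pancreas tests, the dilution test and the scaling test below were chosen after the results were seen, and the thymus test was set before its value was seen. Among the 4 wild-type libraries, 13 of 91 named genes and 0 of 24 list means had a library that stood apart by Dixon's ratio at its 95% critical value. The total counts had none. The ratio was taken on CPM for genes and on mean log2 CPM for lists, so these shares cannot be set side by side. Chance flags about 1 in 20, but many named genes were chosen by their values in these data, so that rate does not hold for them. The mutant group of 3 was not tested. Wild-type 2 stood apart for 8 genes: Cela2a (2495 CPM), Ctrb1 (2384 CPM), Cel (1516 CPM), Prss2 (1365 CPM), Rnase1 (716.7 CPM), Gp2 (224.7 CPM), Klk1 (146 CPM) and Mmp9 (39.99 CPM). Wild-type 4 stood apart for Ly6a (222.7 CPM), Siglec1 (108.9 CPM), Klra7 (13.18 CPM) and Fam183b (0.0396 CPM, which is 3 counts). Wild-type 1 stood apart for Il12b (1.944 CPM).

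A candidate explanation for the pancreatic transcripts in wild-type 1 and 2 is pancreas tissue taken with the spleen. Over 17 list genes with at least 10 counts in both, the log2 ratio of wild-type 2 to wild-type 1 had a median of 5.01 and an SD of 0.515. It ran from 3.48 (Try5) to 5.40 (Pnliprp1), so the enzymes kept only roughly the 1 ratio that a single source would give. The ratio does not show how such material reached each library. Genotype as the source would give the wild-type spleens 1 level, but the pancreas list median of wild-type 1 and 2 lay at least 5.71 log2 units above that of wild-type 3 and 4. Without wild-type 1 and 2, 8 list genes had a median log2 fold change of -1.36 (quartiles -1.46 and -0.79), with Prss2 at -2.02 (adjusted p = 0.0804, edgeR, range 0.000899 to 0.558 over its alternatives). Relative to the wild-type mean, the pancreas list median was -3.766 in wild-type 3 and -5.405 in wild-type 4. In mutants 1 to 3 it was -5.427, -5.53 and -5.491. By this median wild-type 3 stood above the mutants and wild-type 4 was level with them, so the smaller difference was not shared by both. Whether genotype adds anything to it remains open at such low levels.

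For the lower transcripts of B, NK, myeloid, dendritic and stromal cells, dilution of spleen RNA by T lineage RNA alone would lower every other cell type by 1 factor. The stroma list median instead lay at least 3.23 log2 units above the B cell list median in each mutant library. A scaling error shifts all genes of a library by 1 constant, whereas the T cell list median lay at least 6.34 log2 units above the B cell list median within each mutant library. Such gaps within a library do not depend on scaling, so they do not bear on the size of the stromal or myeloid decreases. The stroma list median log2 fold change was -1.06 with TMM, -1.31 with library size alone and -0.97 without globin genes. Dilution and scaling as part of the smaller stromal and myeloid decreases remain open. So do a loss of B, NK, myeloid, dendritic and stromal cells with the genotype and a change in their number with spleen enlargement, which were not tested.

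For the higher transcripts of immature T cells, thymus tissue taken with the spleen would bring thymic epithelial genes. Over 7 such genes with at least 10 counts, the median log2 fold change was -1.52. Ccl25, the most abundant member in the mutants, was the only one above 0 and passed in the direction thymus tissue would give (1.22, SE 0.26, adjusted p = 0.00581, edgeR). These genes had low levels, at most 5.44 CPM. Foxn1, Krt5 and Fezf2, list genes left out of that median, had 0 counts in every library. Immature T cells within the spleen, with the genotype, remain an open hypothesis, and their number was not measured.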

How the results depend on the processing

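The fits without wild-type 1 and 2, without mutant 1 and wild-type 3, with an erythroid covariate and with 1 gene of each identical set were chosen after seeing the data. No call of the 8724 changed genes turned direction while called under any of the 25 alternatives for genes. The counts of genes higher or lower stayed within 1.5 times, except 2924 lower genes at an adjusted p under 0.01 and 2329 genes at least 2-fold lower under the stricter filter, which tests fewer genes. The labels give no pairing by replicate number. Deviations from the group mean correlated at 0.042, -0.186 and 0.101 for libraries of the same number and at -0.226 to 0.206 for different numbers. These values show no pairing but cannot exclude it. With the replicate block 2950 genes rose and 3140 fell. Without wild-type 1 and 2, 2923 rose and 3011 fell, and without mutant 1 and wild-type 3, 4643 and 4283. With an estimated correlation 0 lists were higher and 0 lower. Neutrophil genes also lost their call with fry, and inflammatory cytokines at an adjusted p under 0.01. DESeq2, the exact test and the robust prior give no list result of their own.

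Brca1 reached 1.55 without wild-type 1 and 2. Vav1 stood at -0.52 with library size alone and at 0.062 without mutant 1 and wild-type 3. Reversed values all belong to uncalled results, and the cause was not tested. With sample weights Car1 was at -0.78, Cpox at -0.15, Xist at 0.069, the erythroid list at -0.90 and the heme list at -0.49. Without mutant 1 and wild-type 3, Car1 was at -0.23, Cpox at -0.22, Alas1 at 0.06, Xist at 0.12, the erythroid list at -1.38 and the heme list at -0.76. Without wild-type 1 and 2, Bpgm was at 0.80 and Xist at 0.27, and with the replicate block Xist was at 0.25. Without a filter the fat, liver and muscle list was at 0.14. Leaving out 1 library gave -0.30 to 0.021 for Alas1, -0.79 to 0.53 for Xist, -1.10 to 1.11 for the erythroid list and -4.37 to -0.42 for the fat, liver and muscle list, whose test direction turned while its median stayed negative. Of 2233 values for named genes, 2147 kept direction and side of the threshold, 60 lost the call, 11 gained it and 15 reversed. Of 598 list values, 556, 18, 16 and 8 did so. Depth limits genes near 0 counts, and DESeq2 gave no p for the pancreas list members.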

Other observations

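The genes and lists of the first paragraphs, and the test of transcripts private to 1 spleen, were chosen after values had been seen, while the chromosome tests and the counts over other splits were set before their values were seen, the test of shared machinery genes once the chromosome medians were known. Genes of antigen presentation on MHC class I fell in 7 of 10 members and rose in 0, with a median log2 fold change of -1.43 (camera adjusted p = 0.0261 over 4 added lists, but adjusted p = 0.171 with an estimated correlation). H2-K1 and H2-D1, the classical heavy chains, fell by 3.65 (SE 0.45) and 3.00 (SE 0.40), Nlrc5, their transcriptional activator, by 4.11 (SE 0.67), and B2m, the light chain, by 1.17 (SE 0.20). Tap2 (0.41), Psmb8 (0.41) and Psmb10 (-0.24) did not pass in edgeR.

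Of 14 tested genes of the BCL2 family 8 fell and 3 rose, and the list was not called (median -0.75, camera adjusted p = 0.175). Bcl2 and Mcl1, which block cell death, fell by 3.09 (SE 0.23) and 1.36 (SE 0.14), and Bad and Bid, which promote it, rose by 0.96 (SE 0.18) and 0.84 (SE 0.20), as did Bak1, at 146 ± 18.9 CPM in the mutant and 66.1 ± 8.60 CPM in wild type. Other promoters fell, Bcl2l11 by 0.50 (SE 0.13) and Bok by 1.46 (SE 0.49), and the blocker Bcl2l1 stood at 0.074 (SE 0.72). Among 12 tested transcription factors of T cell leukaemia 2 rose, Myc (2.15, SE 0.22) and Myb (2.72, SE 0.32), and 5 fell, and that list was not called (median -0.98, camera adjusted p = 0.252). The thymic epithelium list was not called either (median -1.52, camera adjusted p = 0.34). Tnfrsf8, which encodes the CD30 receptor, stood at 16.8, 36.6 and 61.5 CPM in the mutants and at 0.46 to 0.815 CPM in wild type. Trp53 rose by 0.93 (SE 0.14, adjusted p = 0.00119, edgeR).

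Some transcripts differed widely between mutant spleens. Il2ra, the high-affinity IL-2 receptor chain, stood at 28.5, 233 and 1222 CPM and at 15.1 to 15.8 CPM in wild type. Ptcra, the partner chain of the early T cell receptor, stood at 4.49, 148 and 158 CPM, and Ccr9 at 195, 8.64 and 121 CPM. Dsp, Dsc2 and Dsg2, desmosome genes, stood at 199, 158 and 150 CPM in mutant 3 and at most 1.55 CPM in the other mutants, with Dsc2 at 10.9 to 21.7 CPM in wild type, and H19, an imprinted transcript, at 119 CPM in mutant 3 and at most 5.13 in the other mutants. The hypothesis that each mutant spleen holds its own expanded cells was tested by counting genes at 10 CPM or more and 8-fold above both other libraries of a group. Mutant 1 had 58, mutant 2 had 7 and mutant 3 had 38. Of these, 34, 5 and 15 came within 8-fold of that level, or above it, in a wild-type library, such as Specc1 (280 CPM in mutant 1, 249 in wild-type 2) and Sorl1 (44.9 CPM in mutant 1, 177 to 245 in wild type), so they are not private to the mutant spleen. Wild-type 3 and 4 had at most 2, wild-type 1 up to 13 with 11 of the pancreas list, and wild-type 2 up to 92 with 21 of the erythroid and 12 of the pancreas list. Since wild-type 1 and 2, whose counts held pancreas or erythroid list genes, reached the count of mutant 2, the counts leave the hypothesis open.

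Genes of chromosome 15, which carries Myc, were shifted upward in each mutant library. Over 474 chromosome 15 genes with a mean of at least 5 CPM, the median log2 ratio to wild type, centred on all 11313 such genes, was 0.311, 0.345 and 0.471 in mutants 1 to 3 and between -0.058 and 0.025 in the wild-type libraries. Among 10000 random gene sets of that size the highest medians were 0.187, 0.26 and 0.272, a description across genes, which are not independent. A gain of the whole chromosome is a hypothesis in line with the values of mutant 3, the library above the 0.4 set for it, where 4 consecutive parts stood at 0.391, 0.505, 0.685 and 0.346. The highest wild-type median of any chromosome was 0.124. The parts stood at 0.304, 0.322, 0.37 and 0.251 in mutant 1 and at 0.166, 0.47, 0.718 and 0.372 in mutant 2, whose first part is under the 0.2 set for each. Cell type makeup cannot be told apart from it. The 33 chromosome 15 genes picked by symbol from families of shared cell machinery had medians of 0.323, 0.185 and 0.52. The lowest is under the 0.3 set to exclude cell type makeup, and the same kind of genes reached -0.52 on chromosome X in mutant 3. A symbol does not ensure equal use in every cell type. Chromosome 1 stood at -0.106, -0.194 and -0.263 and chromosome 18 at 0.163, 0.324 and -0.225 in mutants 1 to 3, with no copy number measured. In mutant 3 chromosome 1 lay below the lowest random median of its size (-0.213). For chromosome 18 in mutant 2 and chromosome 5 in mutant 3 (0.254), 2 and 1 of 10000 random sets reached the value. Chromosome 15 is thus not the only one at or beyond the edge of the random sets.

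Of the 35 splits of the 7 libraries into 3 and 4, 1, the real one, gave as many as 8724 changed genes, and the highest of the others gave 0 by edgeR, with up to 4193 at an unadjusted p under 0.05. For genes changed at least 2-fold 1 split, the real one, reached 6116 and the highest other gave 0. Only the real split reached either count, which is a share under 0.05 of the 35 splits. The other splits all mix the genotypes, which adds their difference to the spread within groups, so 0 calls there cannot by itself exclude chance. For gene lists 18 splits, the real one included, reached the 16 called in the real split, and the highest other gave 22, so chance was not excluded for the number of lists called. Splits that mix the genotypes carry part of their difference, so this count cannot decide the question.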
